A study of Mus musculus with 6 samples.

How the data were processed

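RNA of L929 mouse fibroblasts from co-culture with tumour cells was sequenced on an Illumina NovaSeq, in 3 Biotin-negative and 3 Biotin-positive libraries. The cells were lysed in TRIzol and the RNA integrity was read on an Agilent Bioanalyzer. Per the labels, reads were trimmed with cutadapt 1.9.1, aligned with HISAT2 2.2.1 to GRCm39 and counted with HTSeq 0.6.1. The deposited values are in FPKM, fragments scaled by gene length and library size, with 1 column per library. The program that made the FPKM values, the denominator of the scaling and the strandedness are not stated in the labels. The meaning of the abbreviation that the labels use for the tumour cells is not given there either, nor is the way in which biotin was attached and the cells were divided.

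The file holds 21929 genes, all of them named protein-coding in it, of which 4871 were at 0 in every library. In it 31 symbols stood for more than 1 gene, so genes were handled by identifier. FPKM is not a count, and the values of low genes showed no steps of single reads, so reads per library could not be recovered and the depth is unknown. No interval that needs the depth is given. The precision of a value is its SD over the 3 libraries of a group.

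Values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 11029. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Groups came from the labels. The replicate numbers were not used as pairs, since the labels do not say that equal numbers belong together.

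Before the data were examined, 37 gene lists with 799 entries and 780 distinct genes were fixed. Of the distinct genes 12 had no match in the file and 7 were matched through their current symbol. The 30 lists with at least 5 tested members were tested with camera of limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation and fry were run as alternatives. Named genes were chosen by a rule fixed at the same time. It takes Yap1 and Ctrb1 from the title of the series. It adds the 10 genes with the largest rise and the 10 with the largest fall among those that passed without overlap between the groups and with a mean of at least 5 FPKM in the higher group, leaving out provisional gene names and pseudogenes. It also adds up to 4 passing members per list with the largest change, or the 2 highest tested members where none passed. Some of the genes this rule takes are not reported here. The share of mitochondrial FPKM was compared with an exact permutation test in scipy 1.17.1.

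The procedure was tested on simulated data with 200 changed genes among 11029. At log2 differences of 0.25, 0.5, 1 and 2, limma recovered 44, 96, 94 and 98% of the 50 genes of each size, and 6.74% of its calls were false. In the real data 73.9% of the tested genes passed. The simulation changed far fewer, so these percentages need not hold for the real calls. Camera called 2 of 2 moved lists and 0 of the unmoved ones among 20 simulated lists. In the real data camera called 14 lists at its preset correlation and 0 with an estimated one. The simulated genes varied independently of each other, so the simulation cannot show which correlation setting is right. Its result need not hold for the real list calls.

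Near-identical matches of a gene were searched with blastn 2.17.0 between annotated transcripts of the GENCODE vM21 release, from the longest protein-coding transcript of each gene. Alignments of at least 100 bases and 98% identity were joined, and a gene counted as having a near-identical copy where they covered at least 50% of the transcript. A first run had used the longest transcript of any type. The vM21 release is on an older genome build, so only its sequences and names were used, and all coordinates are those of the deposited file.

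Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum of 5 FPKM, scaling by the median of ratios, quantile normalization, rescaling to an equal sum per library, eBayes without a trend and with a robust prior, the replicate number as a term in the model, leaving out each library in turn, and a log2 threshold of 1. Leaving out genes at 0 in every library of a group was added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table in version 1.17.8.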

Results

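The series holds RNA-seq of L929 cells, a mouse fibroblast line, that were kept in co-culture with tumour cells and divided by a biotin mark. The 3 Biotin-positive libraries come from L929 cells that had interacted with the tumour cells, and the 3 Biotin-negative libraries come from L929 cells that had not. The labels give 1 comparison, between these 2 groups, and the title of the series ties it to the transcriptional coactivator YAP and the digestive protease CTRB1. Each library gives an FPKM value for 21929 genes, with coordinates on GRCm39. The FPKM values of a library summed to between 337771 and 356681, and 10724 to 10862 genes per library reached 1 FPKM. Reads per library are not part of these values, so the sequencing depth is unknown. Pearson correlations of log2(FPKM + 1) between libraries, taken across genes, lay between 0.998 and 0.999 within a group and between 0.977 and 0.978 across the groups. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values below are mean FPKM ± SD with n = 3 libraries per group, the Biotin-negative group first, and log2 differences are on the log2(FPKM + 1) scale, which understates changes of low genes. Genes given by their means without an SD were named after their values were seen. Rose and fell mean higher and lower in the Biotin-positive group, since no library is labelled as taken before contact.

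The largest rises in Biotin-positive cells among genes of 5 FPKM or more included Rhob, a small GTPase, from 0.0513 ± 0.0523 to 36.3 ± 0.845 FPKM, and Tmsb4x, an actin-monomer-binding peptide, from 0.145 ± 0.0585 to 36.0 ± 2.38 FPKM. Anxa8, a calcium-dependent phospholipid-binding protein, rose from 0.0724 ± 0.0241 to 19.8 ± 0.129 FPKM, and the tetraspanin Cd9 from 0.602 ± 0.195 to 29.4 ± 1.33 FPKM. The keratins Krt7 and Krt8, intermediate filament proteins of simple epithelia, rose from 0.236 ± 0.0759 to 24.7 ± 1.18 FPKM and from 0.0362 ± 0.0153 to 20.8 ± 0.355 FPKM. A share of 51.8% of the Krt8 transcript has a near-identical match in other annotated genes, so its level is uncertain. Krt7 and Krt8 were the only 2 of 25 epithelial markers that reached testing. Rab34 was listed at 0 in all 3 Biotin-negative libraries and at 12.1, 12.4 and 14.04 FPKM in the Biotin-positive ones. The largest falls included the matrix proteoglycan Prelp from 35.6 ± 1.11 to 1.51 ± 0.0423 FPKM and the secreted glycoprotein Lrg1 from 18.8 ± 0.986 to 0.506 ± 0.0639 FPKM. They also included the collagen chains Col6a2 (216 ± 7.84 to 14.7 ± 0.514) and Col6a1 (300.4 ± 8.55 to 24.6 ± 0.667), fibronectin, Fn1 (2017 ± 84.6 to 172 ± 4.53), and ceruloplasmin, Cp (15.8 ± 0.640 to 1.18 ± 0.320). Of 11029 genes tested with limma, 4168 were higher and 3985 lower in Biotin-positive cells at an adjusted p of 0.05, and 583 of the former and 376 of the latter had a log2 difference of at least 1. The 2 groups did not overlap for 76.9% of the tested genes, where chance gives 10%.

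**Figure D1:**
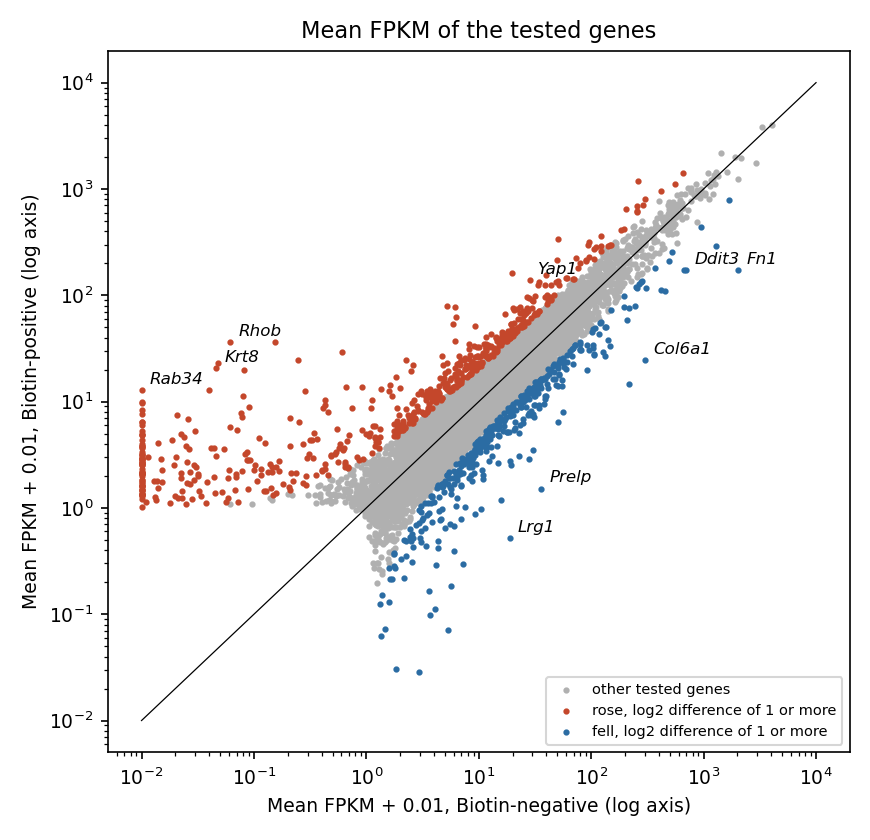
Mean FPKM of the 11029 tested genes in the Biotin-positive (vertical) against the Biotin-negative (horizontal) libraries, both on log axes after adding 0.01, with the diagonal of equal values. The 583 genes that rose and the 376 that fell by a log2 difference of 1 or more are coloured, and the genes near 0 FPKM in the Biotin-negative libraries, such as Rab34, form the column at the left edge.

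Yap1, the gene of the YAP coactivator on chromosome 9 (7931999 to 8004596, ENSMUSG00000053110), rose 4.84-fold, from 28.5 ± 0.429 to 138 ± 5.00 FPKM (log2 difference 2.23, SE 0.0347, limma adjusted p = 1.15e-09), with every Biotin-positive library above every Biotin-negative one. The gene of its paralog TAZ, Wwtr1, fell from 21.0 to 18.0 FPKM. Among 18 tested YAP/TAZ-TEAD targets, genes that TEAD transcription factors switch on together with YAP or TAZ, 13 rose, 3 fell and 2 did not pass. The matricellular gene Ccn1 rose from 19.5 ± 0.458 to 164 ± 3.86 FPKM and the receptor tyrosine kinase gene Axl from 38.8 ± 0.308 to 124 ± 2.64 FPKM. Ccn2 and Foxf2 were listed at 0 in every Biotin-negative library, while Ccn2 was at 1.97, 1.40 and 1.76 FPKM and Foxf2 at 2.94, 2.22 and 2.88 FPKM in the Biotin-positive ones. The targets that fell were Gadd45a (158 to 106 FPKM), Rbms3 (3.46 to 1.80) and Ccdc80 (1.66 to 0.878), and Arhgef17 and Asap1 did not pass. The list was called higher by camera (median log2 difference 0.73, adjusted p = 0.00702), with an adjusted p = 0.326 with an estimated correlation. Of 22 Hippo pathway components, 14 rose, 3 fell and 5 did not pass. Besides Yap1, the kinase gene Stk4 rose from 10.1 ± 0.477 to 22.2 ± 0.575 FPKM and the scaffold gene Wwc1 from 0.0490 ± 0.0429 to 1.91 ± 0.0615 FPKM. The kinase gene Map4k4 fell from 92.7 ± 3.32 to 54.1 ± 1.38 FPKM and Amotl1 from 34.4 to 21.7 FPKM. The kinases and scaffold named here act upstream of YAP as its inhibitors in the textbook pathway, so the list mixes YAP with its regulators. Its camera call (median 0.32, adjusted p = 0.0416) was lost with an estimated correlation (adjusted p = 0.439), among genes of at least 5 FPKM (adjusted p = 0.18), without Biotin-negative replicate 3 (adjusted p = 0.0655) and without Biotin-positive replicate 3 (adjusted p = 0.0519). Over 17 alternatives that kept the preset correlation, its camera adjusted p ranged from 0.023 to 0.18. In these same libraries the epithelial keratins Krt7 and Krt8 rose, as given above.

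Ctrb1, the gene of chymotrypsinogen B1 on chromosome 8 (111686519 to 111691010, ENSMUSG00000031957), was listed at 0 in each Biotin-negative library and at 0.0927, 0.0393 and 0.0521 FPKM in the Biotin-positive ones, below the 1 FPKM needed for testing. Of the 20 digestive proteases and acinar enzymes fixed as a list, 1 reached testing: the elastase gene Cela1 fell from 26.9 ± 0.986 to 14.5 ± 1.69 FPKM (limma adjusted p = 9.93e-06).

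**Figure D2:**
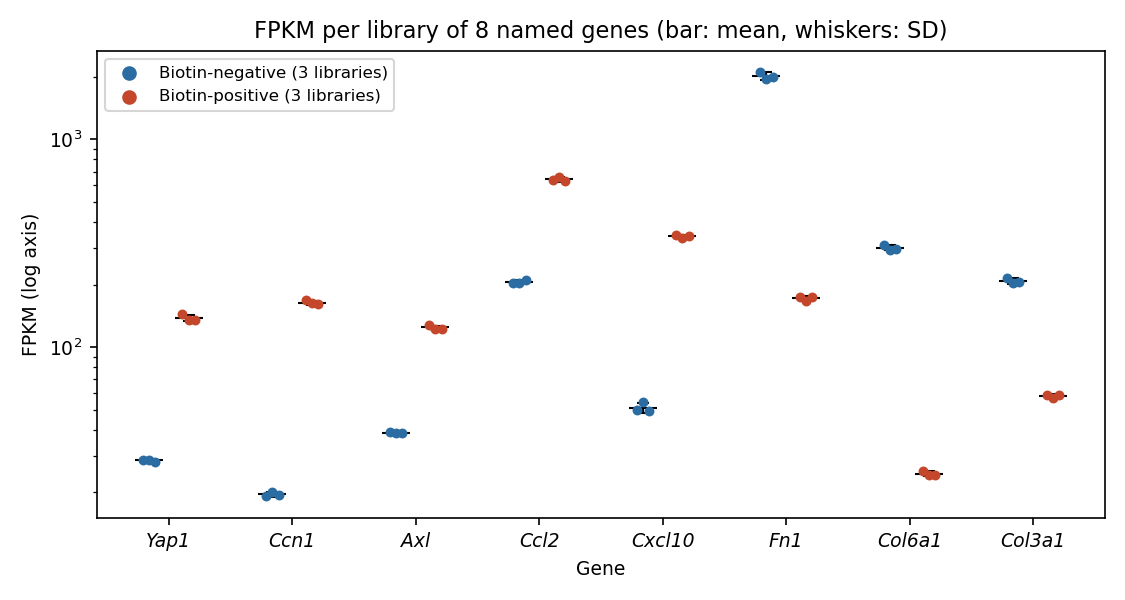
FPKM on a log axis of 8 named genes in the 3 Biotin-negative and 3 Biotin-positive libraries, 1 point per library, with a bar for the mean and whiskers for the SD. Yap1 rose from a mean of 28.5 to 138 FPKM and Fn1 fell from 2017 to 172 FPKM, with no overlap between the groups in any of the 8 genes.

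Extracellular matrix transcripts fell in Biotin-positive cells. Of 21 tested fibrillar matrix and crosslinker genes, 18 fell, 2 rose and 1 did not pass. Beside the collagen VI chains and fibronectin, Col3a1 fell from 208 ± 5.94 to 58.2 ± 0.943 FPKM, a ratio of 0.280. Thrombospondin 1 (Thbs1, 3.59 to 11.1 FPKM) and the lysyl oxidase relative Loxl3 (31.7 to 37.5 FPKM) rose, and Loxl2 (16.8 and 17.5 FPKM) did not pass. Of 10 basement membrane genes 9 fell, among them Col18a1 from 80.0 ± 2.24 to 30.6 ± 0.835 FPKM, the laminin chains Lama5 from 34.5 ± 1.43 to 15.05 ± 0.498 FPKM and Lamb1 from 79.6 ± 3.05 to 36.7 ± 1.13 FPKM, and Col4a5 did not pass. The camera adjusted p was 1.59e-06 for fibrillar matrix (median log2 difference -1.01) and 0.000444 for basement membrane (median -0.63), with an adjusted p = 0.326 and an adjusted p = 0.393 with an estimated correlation. Contractile myofibroblast genes went both ways, 8 up and 4 down of 12, and the list was not called (camera adjusted p = 0.12). The calponin-family gene Tagln2 rose from 93.8 ± 2.29 to 294 ± 8.23 FPKM and tropomyosin, Tpm1, from 68.7 ± 2.35 to 133 ± 3.02 FPKM. The receptor gene Pdgfrb fell from 33.9 ± 2.14 to 14.4 ± 0.456 FPKM and Mylk, the myosin light chain kinase gene, from 3.86 ± 0.124 to 1.29 ± 0.0578 FPKM. Of 14 fibroblast identity markers, 5 rose, 8 fell and 1 did not pass (camera adjusted p = 0.241). Dermatopontin, Dpt, fell from 27.7 ± 0.571 to 2.86 ± 0.284 FPKM, Mfap5 rose from 1.87 ± 0.212 to 6.59 ± 0.961 FPKM and vimentin (Vim) rose from 658 to 1418 FPKM. Twist1 was listed at 0 in every Biotin-negative library and at 6.52, 6.78 and 5.92 FPKM in the Biotin-positive ones. Krt7 and Krt8 rose in the libraries in which the matrix genes fell.

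Cell cycle transcripts rose. All 25 tested genes of the S phase and DNA replication list and all 25 of the G2 and mitosis list were higher in Biotin-positive cells. The ribonucleotide reductase subunits Rrm1 and Rrm2 rose from 28.02 ± 0.820 to 93.5 ± 2.70 FPKM and from 50.3 ± 2.07 to 135 ± 3.12 FPKM. Ccne1, cyclin E1, rose from 8.61 ± 0.210 to 21.5 ± 0.912 FPKM. Among mitotic genes, cyclin A2 (Ccna2) rose from 20.7 ± 2.30 to 72.6 ± 0.857 FPKM, the kinase gene Aurka from 12.9 ± 0.564 to 43.4 ± 0.160 FPKM and Hmmr from 6.68 ± 0.277 to 23.2 ± 1.66 FPKM. Ccnb1, which has a near-identical match for 51.9% of its transcript, rose from 19.99 ± 0.854 to 75.1 ± 2.90 FPKM. The median log2 difference was 0.82 for S phase (camera adjusted p = 5.11e-09) and 1.42 for G2 and mitosis (camera adjusted p = 6e-12), with an adjusted p = 0.232 and an adjusted p = 0.219 with an estimated correlation. Of 20 p53 targets, 16 rose, 2 fell and 2 did not pass, and 17 rose when adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a rose from 11.6 ± 0.723 to 26.8 ± 1.73 FPKM and Phlda3 from 18.8 ± 0.290 to 39.5 ± 0.922 FPKM. Bbc3 (13.3 to 10.9 FPKM) and Btg2 (4.19 to 3.50 FPKM) fell. Pmaip1 was listed at 0 in every Biotin-negative library and at 3.25, 2.47 and 2.95 FPKM in the others. The list was called higher (camera adjusted p = 0.000933), with an adjusted p = 0.232 with an estimated correlation. The keratin rise was measured in these same libraries.

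**Figure D3:**
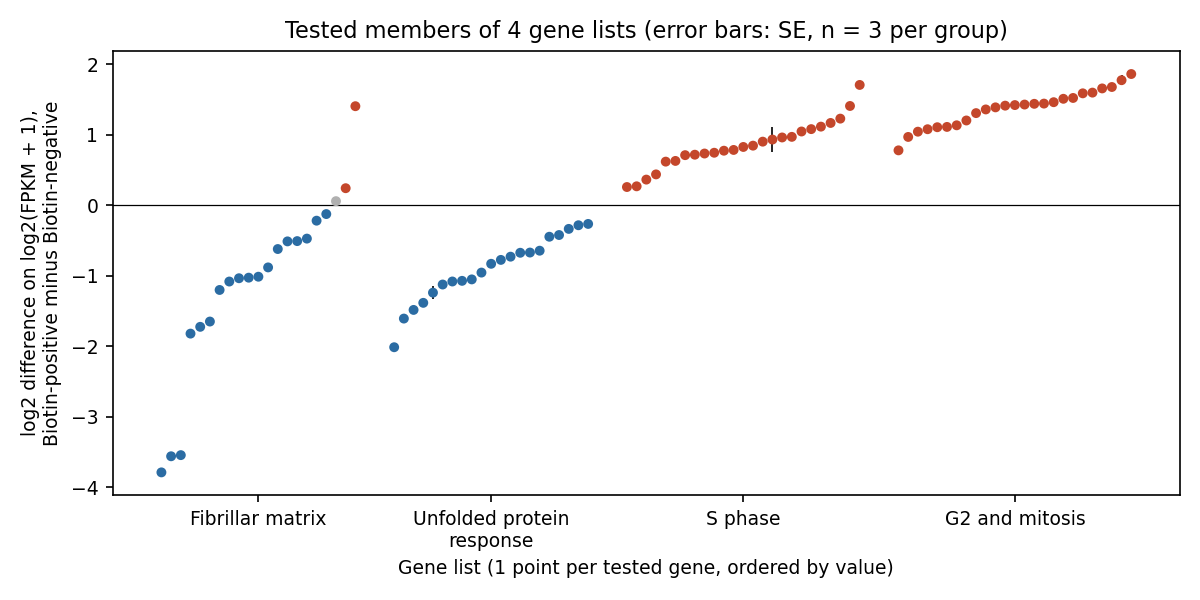
The log2 difference between Biotin-positive and Biotin-negative libraries for each tested member of 4 gene lists, with the SE as error bars. All 25 S phase genes and all 25 G2 and mitosis genes lie above 0, all 21 unfolded protein response genes lie below 0, and 18 of 21 fibrillar matrix genes fell.

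All 21 genes of the unfolded protein response list fell. The list holds genes of protein folding and quality control in the endoplasmic reticulum, and transcription factor genes of this response. Ddit3, the stress-induced transcription factor CHOP, fell from 694 ± 12.9 to 171 ± 8.14 FPKM, Herpud1 from 246 ± 5.86 to 80.0 ± 2.55 FPKM, Sdf2l1 from 215 ± 3.78 to 76.3 ± 2.96 FPKM and the transcription factor gene Xbp1 from 134 ± 2.52 to 50.8 ± 1.06 FPKM. The list had a median log2 difference of -0.83 (camera adjusted p = 1.15e-09), with an adjusted p = 0.147 with an estimated correlation. Amino acid stress genes under ATF4 were mixed, with 6 up, 10 down and 2 not passing of 18 (camera adjusted p = 0.18). Trib3 fell from 197 ± 3.72 to 78.2 ± 3.10 FPKM and Aldh1l2 from 104 ± 1.52 to 34.0 ± 1.66 FPKM, while the serine synthesis gene Psat1 (164 to 218 FPKM) rose. Of 21 cholesterol synthesis genes, 18 rose, Mvd fell (10.8 to 8.72 FPKM) and 2 did not pass. The isomerase gene Idi1 rose from 5.33 ± 0.735 to 19.6 ± 0.728 FPKM and Hsd17b7 from 1.26 ± 0.245 to 4.12 ± 0.221 FPKM (camera adjusted p = 2.03e-05 for the list, median 0.77), with an adjusted p = 0.232 with an estimated correlation. Of 26 nuclear genes of oxidative phosphorylation, 24 rose and 2 did not pass, and 25 rose when adjusted over the list alone. Sdhd, a subunit of succinate dehydrogenase, rose from 43.4 ± 3.31 to 97.1 ± 1.71 FPKM and Ndufa4 from 81.1 ± 5.93 to 133 ± 0.178 FPKM (camera adjusted p = 4.32e-06 for the list, median 0.44), with an adjusted p = 0.232 with an estimated correlation. Glycolysis and hypoxia genes went both ways, 13 up and 10 down of 25. The carbonic anhydrase gene Car9 fell from 106 ± 0.253 to 27.4 ± 0.915 FPKM and Ndrg1 from 198 ± 4.75 to 98.3 ± 2.05 FPKM. The list's median was 0.12 while its mean was -0.06 and its camera direction was down (adjusted p = 0.942). The NRF2 list held 12 rises and 6 falls among 19 genes (camera adjusted p = 0.247). The thioredoxin reductase gene Txnrd1 rose from 50.6 ± 2.75 to 91.4 ± 3.20 FPKM and the glutathione transferase gene Gstm1 fell from 310.4 ± 8.71 to 117 ± 2.01 FPKM. Krt7 and Krt8 rose beside these metabolic changes.

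Inflammatory cytokine and interferon-response transcripts were mostly higher. Of 13 tested inflammatory fibroblast cytokines, 10 rose and 3 fell. The chemokine gene Ccl2 rose from 206 ± 4.03 to 643 ± 16.3 FPKM and Cxcl5 from 0.0605 ± 0.0664 to 5.40 ± 1.00 FPKM. Il6 rose from 2.63 to 10.3 FPKM and Lif from 3.60 to 9.48 FPKM. The complement gene C3 fell from 6.07 ± 0.303 to 0.382 ± 0.122 FPKM, the siderophore-binding gene Lcn2 from 127 ± 3.13 to 29.0 ± 0.938 FPKM and Saa3, an acute-phase gene, from 8.76 to 3.31 FPKM. The camera call (median 1.15, adjusted p = 0.0292) was lost with an estimated correlation (adjusted p = 0.326) and among genes of at least 5 FPKM (adjusted p = 0.115, in a range from 0.00807 over the 17 alternatives). Of 26 interferon-response genes, 20 rose, 4 fell and 2 did not pass. Cxcl10 rose from 51.0 ± 2.81 to 342 ± 4.34 FPKM, Rsad2 from 49.7 ± 1.22 to 214 ± 5.31 FPKM and Ifit2 from 14.6 ± 0.874 to 36.8 ± 1.16 FPKM. Those that fell were Oas2 (103 to 48.3 FPKM), Isg15 (551 to 468), Rtp4 (97.3 to 65.2) and Irf9 (44.7 to 32.8). The list was called higher (median 0.59, camera adjusted p = 0.000463), with an adjusted p = 0.326 with an estimated correlation. The NF-kB response list was not called, with 6 up, 5 down and 3 not passing of 14, a median of -0.09 against a mean of 0.15, and an upward camera direction (adjusted p = 0.942). Tnfaip3 rose from 2.67 ± 0.196 to 6.84 ± 0.522 FPKM and Nfkbia, which encodes the inhibitor IkB-alpha, from 24.0 ± 0.741 to 30.8 ± 0.625 FPKM. Antigen presentation was mixed as well, with 5 up, 7 down and 2 not passing of 14 (camera adjusted p = 0.428). Cd274, the gene of the checkpoint ligand PD-L1, rose from 1.14 ± 0.113 to 5.94 ± 0.409 FPKM, while the nonclassical class I gene H2-T23 fell from 142 ± 3.83 to 37.7 ± 0.697 FPKM. These libraries are the ones in which Krt7 and Krt8 rose.

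Camera called neither the TGF-beta response list nor the growth factor list. Fry called both (adjusted p = 0.000739 and 4e-04), but it called 28 of the 30 lists, so this does not single them out. Smad7, which encodes an inhibitor of TGF-beta signalling, rose from 1.92 ± 0.107 to 5.29 ± 0.495 FPKM and Skil from 5.55 ± 0.525 to 10.6 ± 0.139 FPKM, while Tgfbi fell from 132 ± 5.35 to 26.6 ± 1.17 FPKM. Of 19 TGF-beta response genes 13 rose, 4 fell and 2 did not pass, with 5 falls adjusted over the list alone (camera adjusted p = 0.13). The EGF-family ligands Areg and Ereg rose from 0.643 ± 0.105 to 13.9 ± 0.848 FPKM and from 3.40 ± 0.0496 to 11.4 ± 0.401 FPKM, and Pdgfc from 1.30 ± 0.196 to 5.50 ± 0.262 FPKM, in a growth factor list with 8 rises, 6 falls and 2 not passing of 16 (camera adjusted p = 0.634). Among 16 metalloproteinase and inhibitor genes, 7 rose, 8 fell and 1 did not pass. Adamts1 rose from 0.690 ± 0.170 to 4.88 ± 0.291 FPKM, Mmp19 fell from 10.6 ± 0.525 to 2.26 ± 0.111 FPKM and Adamts2, a procollagen-processing enzyme, fell from 28.2 ± 1.96 to 7.73 ± 0.107 FPKM. That list's median was -0.09, its mean 0.07 and its camera direction down (adjusted p = 0.885), while fry gave the direction up. The Notch, Wnt and cell-contact list held 6 rises and 6 falls among 14 genes (camera adjusted p = 0.989), with a median of -0.08 and a mean of 0.09. The adhesion gene Nectin2 rose from 21.8 ± 1.13 to 49.3 ± 1.98 FPKM and the Wnt inhibitor gene Nkd1 fell from 6.04 ± 0.242 to 1.68 ± 0.0986 FPKM. The keratin rise stood beside these changes as well.

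The cell competition list, drawn up because the title speaks of competitive fitness, was not called (camera adjusted p = 0.0825). Of its 10 tested genes 6 fell, 4 did not pass and 0 rose. Sparc fell from 523 ± 21.0 to 256 ± 10.6 FPKM, the polarity gene Dlg1 from 24.0 ± 0.473 to 18.6 ± 0.275 FPKM and Myc from 184 ± 6.15 to 148 ± 2.204 FPKM. Cacfd1, the mouse gene of the Flower fitness marker, stood at 13.6 and 13.4 FPKM and did not pass. Myc-linked ribosome biogenesis genes were split, with 8 up, 8 down and 7 not passing of 23 (camera adjusted p = 0.695). The polyamine enzyme gene Odc1 rose from 161 ± 3.37 to 280 ± 5.03 FPKM and Rrs1 fell from 53.1 ± 1.01 to 33.6 ± 0.876 FPKM.

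Markers of other cell types and of RNA handling were measured in the same way. Of 25 epithelial markers, 2 reached testing, Krt7 and Krt8, and both rose, while Epcam was at 0.0231, 0.0195 and 0 FPKM in the Biotin-positive libraries and Cdh1 was listed at 0 in all 3. Of 6 tested squamous forestomach markers, 4 rose, Col17a1 fell (1.53 to 1.11 FPKM) and Sprr1a did not pass (camera adjusted p = 0.157). Perp and Sox2 were listed at 0 in every Biotin-negative library, with 2.59, 2.59 and 2.50 FPKM and 2.01, 1.81 and 1.60 FPKM in the Biotin-positive ones. Among 3 tested gastric glandular markers Klf5 rose from 6.63 ± 0.397 to 9.72 ± 0.187 FPKM, Sox9 fell from 8.41 ± 0.402 to 3.97 ± 0.143 FPKM and Gata6 did not pass. The 4 tested haematopoietic markers had means under 10 FPKM in both groups, with Cd14 and Lyz2 higher and Coro1a and Cd68 lower. The Cd68 call (limma adjusted p = 0.0402) was lost without Biotin-negative replicate 1 (adjusted p = 0.102), without Biotin-negative replicate 3 (adjusted p = 0.125), without Biotin-positive replicate 2 (adjusted p = 0.0543), without Biotin-positive replicate 3 (adjusted p = 0.136) and with no filter (adjusted p = 0.0833), in a range from 0.0137 to 0.136. Of 2 tested endothelial markers, Plvap fell from 11.02 ± 0.442 to 3.77 ± 0.102 FPKM and Eng rose from 108 ± 4.16 to 121 ± 2.31 FPKM, a call lost under quantile normalization (adjusted p = 0.559, in a range from 0.00117). Immediate early and dissociation genes went 14 up and 6 down of 20, with Ier3 rising from 30.0 ± 0.563 to 89.8 ± 2.34 FPKM and Egr1 falling from 41.4 ± 0.356 to 13.3 ± 0.567 FPKM. Their call (camera adjusted p = 0.0416) was lost with an estimated correlation (adjusted p = 0.454), with no filter (adjusted p = 0.106) and without Biotin-positive replicate 3 (adjusted p = 0.0519), in a range from 0.0227 to 0.106 over the 17 alternatives. Of 16 heat shock genes, 11 rose, 3 fell and 2 did not pass, with 4 falls adjusted over the list alone. The small heat shock gene Cryab rose from 2.61 ± 0.387 to 22.3 ± 1.06 FPKM, and Hspa8, 84.5% of whose transcript has near-identical matches, from 257 ± 8.61 to 604 ± 9.56 FPKM (camera adjusted p = 0.00645 for the list), with an adjusted p = 0.326 with an estimated correlation. Mitochondrially encoded transcripts held 3.75 ± 0.162% of the summed FPKM in Biotin-negative and 3.79 ± 0.0706% in Biotin-positive libraries (exact permutation test, two-sided, p = 0.8, where 0.1 is the smallest p that 3 against 3 allows). Of the 13, 6 rose, 4 fell and 3 did not pass (camera adjusted p = 0.695), and among those that fell mt-Co2 (1612 to 1442 FPKM), with a near-identical match over 99.6% of its transcript, changed sign under quantile normalization. Cytoplasmic ribosomal protein genes rose in 15 of 26 cases, fell in 3 and did not pass in 8, with 14 rises adjusted over the list alone. Near-identical matches cover 99.4, 97.3 and 84.6% of the Rplp1, Rps18 and Rps2 transcripts in that list, so these levels are uncertain. That list was not called (camera adjusted p = 0.0795), but passed without Biotin-negative replicate 3 (adjusted p = 0.0476) and without Biotin-positive replicate 3 (adjusted p = 0.0478), in a range up to 0.261. Of 3 tested replication-dependent histone genes H2bc4 and H2bc8 rose and H1f2 fell, and the level of H2bc8 is uncertain because 61.8% of its transcript has near-identical matches. The nuclear-retained RNA Tug1 stood at 22.8 ± 0.618 and 22.97 ± 0.858 FPKM and did not pass.

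**Figure D4:**
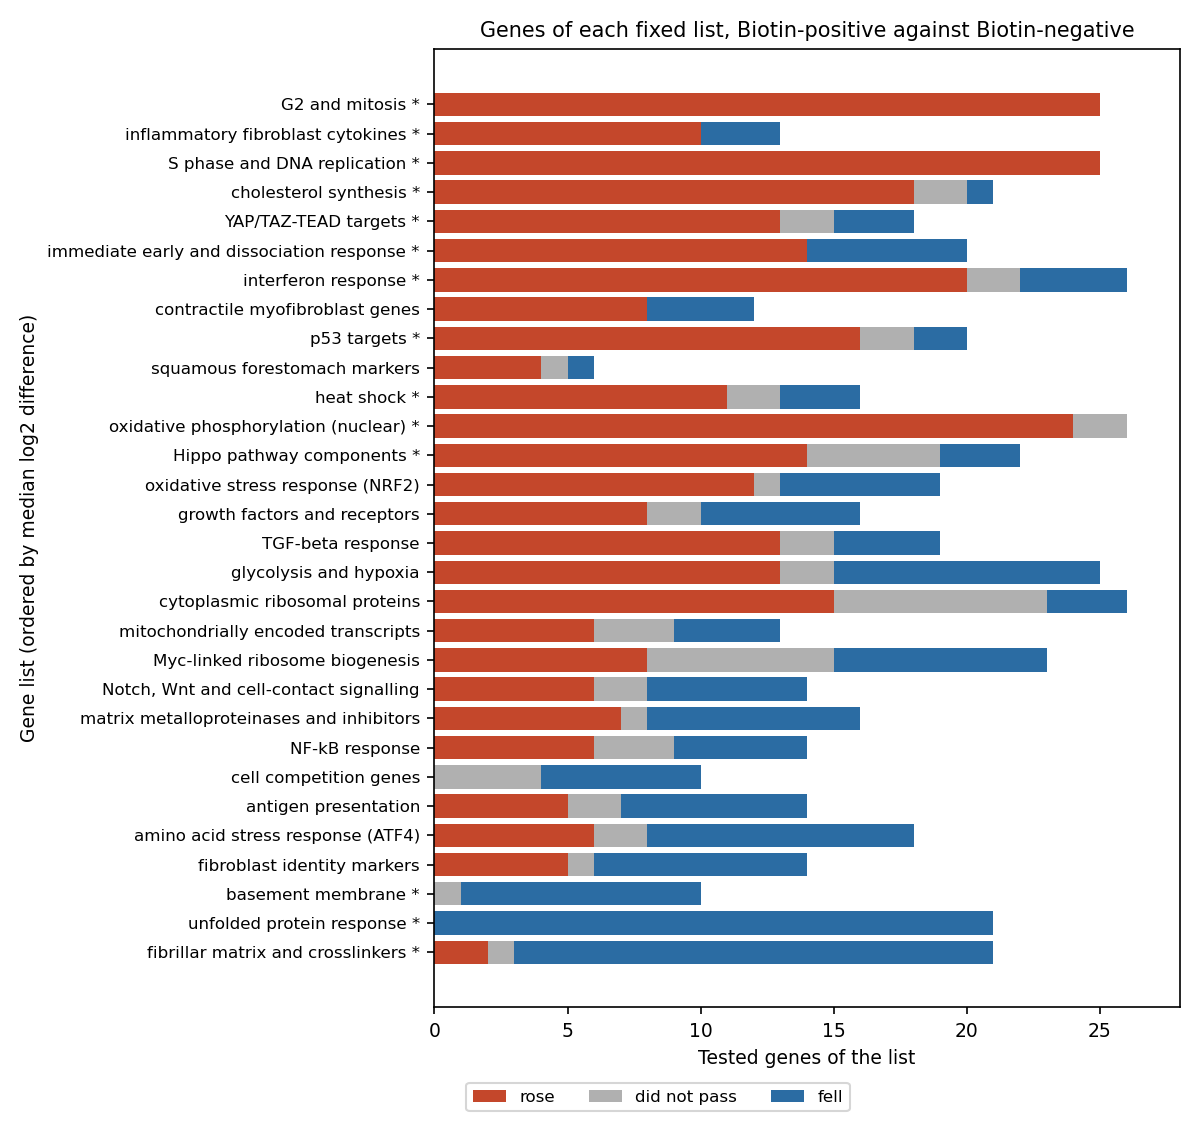
Number of tested genes that rose, fell or did not pass in each of the 30 gene lists with at least 5 tested members, ordered by the median log2 difference, with an asterisk where camera called the list at its preset correlation of 0.01. The 14 called lists are 11 that were higher and 3 that were lower in Biotin-positive cells, and 0 lists were called with an estimated correlation.

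Across the 30 lists with at least 5 tested members, camera with its preset correlation called 14, of which 11 were higher and 3 lower in Biotin-positive cells. With the inter-gene correlation estimated from these 6 libraries it called 0, with 6 lists at an unadjusted p under 0.05, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 28. Counts adjusted over the list alone equalled those over all tested genes in every list except the 5 for which both are given.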

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

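The counts of higher genes, lower genes and called lists stayed within 1.5 times their values in 33 recounts under other pseudocounts, filters, scalings and variance priors, the replicate term and the added alternative, and in 18 recounts without a library. With limma, the number of passing genes ranged from 7690 to 7878 when a library was left out, was 9220 of 17058 tested genes with no filter, and was 6592 of 8577 tested genes at a minimum of 5 FPKM. With a log2 threshold of 1 added, 583 genes were higher and 376 lower, since small differences no longer count. Rescaling to an equal sum per library gave 3686 higher and 4500 lower genes. With the replicate number as a term, 4113 genes were higher and 3927 lower, 7918 of the 8153 calls were kept and the call of Cd68 was lost (limma adjusted p = 0.0663), while deviations from the group mean correlated across genes at 0.0371, 0.0120 and 0.0143 for libraries of the same number, and Biotin-positive replicate 3 correlated best with Biotin-negative replicate 2 (0.0341). Under quantile normalization 1 of the 8153 calls turned to the opposite direction and passed there, and the called mt-Co2 changed sign. No reversal was seen among passing genes taken by the naming rule or among called lists under the alternatives run for them. Of the gene list results, 325 kept their side of the threshold under the other settings and 3 lost it, and without a library 175 kept it, 3 lost it and 2 gained it. Of the named gene results, 1561 kept it and 7 lost it, and without a library 857 kept it and 13 lost it. Camera called 14 lists at its preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05, and the cause was not tested. Fry called 28, since it does not compare a list with other genes. Leaving out genes at 0 in every library of a group, an alternative chosen after seeing the data, gave 8082 passing genes of 10966, and the YAP/TAZ-TEAD list kept its call with a camera adjusted p = 0.0247. The alternative planned for raw counts was not run, since the values are FPKM, and the unknown depth limits what a value of 0 can say.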

Other observations

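The gene families here were chosen after their values were seen, and directions held under each scaling alternative for the genes named. Serpinb genes encode clade B serpins, most of them intracellular inhibitors of proteases. All 13 tested members of their cluster on chromosome 13 (32842092 to 34002794) rose in Biotin-positive cells, of which Serpinb9f and Serpinb9h have near-identical matches over 97.4 and 100% of their transcripts. Serpinb9b rose from 6.31 ± 0.252 to 63.0 ± 1.35 FPKM, Serpinb9e from 1.84 ± 0.0920 to 16.9 ± 0.681 FPKM and Serpinb9 from 10.0 ± 0.672 to 32.9 ± 1.80 FPKM. Of 10 tested annexin genes, whose proteins bind phospholipids in the presence of calcium, 8 rose and 2 fell. Anxa1 rose from 122 ± 1.73 to 365 ± 11.2 FPKM, Anxa2 from 256 ± 4.04 to 688 ± 10.5 FPKM and Anxa3 from 95.3 ± 3.02 to 316 ± 0.605 FPKM, while Anxa6 fell from 49.1 ± 1.12 to 34.6 ± 0.576 FPKM and Anxa9 from 3.97 ± 0.700 to 2.28 ± 0.309 FPKM. Of 10 tested S100a genes, which encode small calcium-binding proteins, 7 rose, 2 fell and S100a16 did not pass, and the levels of S100a4 and S100a11, which rose, are uncertain because 60.6 and 58.1% of their transcripts have near-identical matches. S100a6 rose from 302 ± 19.5 to 797 ± 24.4 FPKM and S100a10, the partner of annexin A2, from 254 ± 8.75 to 626 ± 31.7 FPKM, while S100a1 and S100a14 fell.

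Of the guanylate-binding protein genes, which are induced by interferons, 4 of 5 tested on chromosome 3 rose and all 5 on chromosome 5 fell. Those 5 falls are not fully separate measurements, since Gbp6 and Gbp10 have near-identical matches over 99.96 and 97.8% of their transcripts and the coordinates of Gbp4, Gbp8 and Gbp9 overlap. Gbp2 rose from 7.13 ± 0.330 to 14.4 ± 0.273 FPKM and Gbp3 from 41.1 ± 3.16 to 62.1 ± 1.56 FPKM, while Gbp9 fell from 24.8 ± 0.493 to 6.85 ± 0.657 FPKM and Gbp4 from 6.97 ± 0.186 to 1.63 ± 0.0731 FPKM. Of 7 tested Ly6 genes on chromosome 15, 6 fell, with a near-identical match over 94.1% of the transcript of Ly6c1, among them Ly6a, which encodes the surface antigen Sca-1, from 663 ± 13.5 to 171 ± 4.03 FPKM. Ly6f was listed at 0 in every Biotin-negative library and at 2.16, 2.34 and 3.05 FPKM in the Biotin-positive ones. The inflammatory caspase genes on chromosome 9 all fell, Casp1 from 21.4 ± 1.72 to 10.0 ± 0.650 FPKM, Casp4 from 132 ± 0.737 to 50.04 ± 0.830 FPKM and Casp12 from 31.9 ± 3.54 to 11.2 ± 0.373 FPKM.

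Of the tests that follow, those of RNA from other cells, of mitochondrial transcripts, of Yap1 copy number and of the splits were chosen after the result was seen. A set of 63 genes was listed at 0 in every Biotin-negative library and reached 1 FPKM in every Biotin-positive one, against 0 genes the other way, a difference of 63, and with under 0.1 FPKM in place of 0 the counts were 129 and 3. Low depth in the Biotin-negative libraries is argued against, as 0.0741% of their genes of 1 to 3 FPKM were at 0 in any library, and so are reads shared with near-identical genes, which 7.94% of the 63 genes have against 5.61% of 499 random genes. RNA of cells other than L929 and induction in L929 cells by contact cannot be told apart here. Nor do the libraries show whether the marked L929 cells already differed from the unmarked ones before contact. The counts are the observation itself, the tumour cells' own profile was not analysed here and sequence variants were not tested. The division by biotin would have to let RNA of other cells through. Such RNA could also add to other rises, Yap1 among them, and take up part of a library, which lowers the values of L929 transcripts. The falls, Fn1 among them, therefore share this limit. Fn1 stood at 0.0853 of its Biotin-negative mean and Lrg1 at 0.0269. Dilution alone would give such a ratio only if L929 RNA made up at most about that share of the library. The share of L929 RNA was not measured. Of 25 epithelial markers Krt7 and Krt8 reached 1 FPKM in every Biotin-positive library while Epcam was at 0.0231, 0.0195 and 0 FPKM, and of 25 squamous markers 5 did, against 3 in every Biotin-negative library, with Perp and Sox2 up from 0 and Krt5 at 0 in all 6 libraries. The genes named next are examples from outside these lists and decide nothing here. Crct1, taken by the naming rule, rose from 0.0300 ± 0.0520 to 12.8 ± 1.21 FPKM. Keratin, S100a and Lce genes were named after their values were seen. Of 4 tested keratin genes, Krt7 and Krt8 included, 3 rose and 0 fell. Of 10 tested S100a genes 7 rose and 2 fell. Among them Krt80 rose from 1.99 ± 0.279 to 13.5 ± 0.791 FPKM and S100a7a from 0.199 ± 0.132 to 6.93 ± 0.632 FPKM. S100a14 fell from 2.16 ± 0.411 to 0.733 ± 0.248 FPKM. Lce1g was listed at 0 in every Biotin-negative library and at 6.15, 5.13 and 4.71 FPKM in the Biotin-positive ones. Krt10, at 1.36 ± 0.166 and 1.22 ± 0.192 FPKM, did not pass.

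The 13 mitochondrially encoded transcripts moved apart, with mt-Nd2 at a ratio of 2.28 (422 ± 124 to 962 ± 47.2 FPKM) and mt-Nd6 at 0.715 (423 ± 20.5 to 303 ± 6.27 FPKM). A change in the overall amount of mitochondrial RNA would move them alike, but the highest ratio was 3.19 times the lowest. Reads shared with annotated nuclear copies are argued against as the whole cause, since mt-Nd2 and mt-Nd6 are both among the 6 transcripts without such a copy. The value of mt-Nd2 varied between the Biotin-negative libraries (358, 564 and 343 FPKM). Of the other transcripts without a copy, mt-Cytb stood at a ratio of 1.31 and mt-Nd5 at 0.773. Differences in mitochondrial RNA processing or in the mitochondrial genomes of the cells present stay open and were not tested.

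Yap1 rose 4.84-fold, and a copy gain of its chromosome segment was weighed on its neighbours. The median ratio of the 8 tested genes within 1 Mb was 1.14. Birc2 fell from 11.5 ± 0.186 to 8.92 ± 0.116 FPKM and Tmem123 rose only from 32.3 ± 2.52 to 36.6 ± 0.267 FPKM. If the RNA is all of L929 cells, these values argue against a gain of the whole segment. A gain narrower than this window was not tested. The neighbours Mmp10, Mmp13 and Cep126 were near 0 in the Biotin-negative libraries and rose. A regulated rise of Yap1 in L929 cells and Yap1 RNA of other cells both stay open. Whether Yap1 already differed between the 2 groups of L929 cells before contact is not shown either.

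For the 8153 genes that passed with limma, the 6 libraries allow 10 splits into groups of 3, of which 1, the real one, gave as many genes. The highest of the other splits gave 0 genes with limma, with at most 47 at an unadjusted p under 0.05. Each other split puts libraries of both groups on each side, so the group difference widens its spread. The low counts of the other splits therefore say little about chance, and 10 splits are too few for a share under 0.05.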
